A study of Drosophila melanogaster with 2 samples.

How the data were processed

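Chromatin immunoprecipitation with sequencing was done on embryos of both sexes, aged 0 to 24 hours, of a Drosophila line with Pita fused to eGFP. Per the labels, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an anti-GFP antibody. The labels conflict here: the description names anti-GFP, which is followed in the text, and the antibody field names pita. The labels name biological replicates 1 and 3, which form 1 group of 2 libraries. A control experiment is named in the labels and was not analysed here. Nothing in the labels says more of how the replicates were raised, so their spread may be partly technical.

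The deposited peak lists give a signal per peak, a summit and an interval, on dm6 and dm3. The authors' lists are candidates for each replicate and for the pooled libraries, and the optimal list thresholded by irreproducible discovery rate (IDR), which per the deposited notes was derived from the lists of both replicates and the pooled list. Candidates were called against a control alignment, per the same notes. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal is the authors' own value and was used as deposited. Read depth is unknown, and the intervals below cover the counting of peaks alone. The lists held 30000 candidates each, except that of replicate 3 on dm3, which held 18917.

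The dm6 lists were used for the results, with Ensembl release 115 gene models and the RefSeq sequence of the same assembly, and all dm6 peaks lay within its chromosomes. Transposable elements were left out of the genes. A summit was a promoter summit within 500 bp of an annotated TSS, and otherwise fell in the first that applied of 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. Summits within 100 bp were matched between lists. Other candidates were pooled candidates over 100 bp from any IDR summit. The pooled candidate list was deposited as peaks and background, so these include background regions. Location classes, arms, gene lists and head-to-head genes were compared with Fisher's exact test, the bithorax complex with an exact binomial test, signal with 100000 permutations and 8-mers with an exact McNemar test, all two-sided, with Benjamini-Hochberg adjustment in each family and a threshold of 0.05. Intervals are exact Clopper-Pearson intervals at 95%. Gene symbols of 12 lists were matched with older names, and every written symbol was found.

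The peaks named are the 15 of highest signal, the 10 strongest in the bithorax complex, for each gene list the 3 members of highest promoter signal, the genes pita, Orc4, Ubx, abd-A and Abd-B whatever their value, and the 5 8-mers of lowest p. Gnf1, the stronger summit at pita and the sequence matrix were added after their values were seen. The matrix of 19 bp was learned in 8 rounds from sites around the enriched 8-mers, with a threshold that 5% of flank windows exceed.

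IDR summits within 300 bp of a stronger one are called shoulder summits. They were found when flanks upstream and downstream of the summits, on the plus strand, gave different counts of enriched 8-mers. The planned comparisons and the share of the 19 bp sequence were computed again with them dropped, in the peaks and in the candidates, from the strongest summit down. The overlap of the strongest candidates, the split of the peaks for 8-mers, the signal of peaks with CTCAAACC, head-to-head pairs counted once, gene lists against genes with a candidate, the fold of the CTCF core at promoters and genome-wide matches were not; a summit whose stronger neighbour was itself dropped was kept. Other alternatives were the 669 peaks of higher signal, each replicate alone, other windows and backgrounds, a distance of 200 bp between summits, and the dm3 list.

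The tests were tried on simulated data. Of 2046 8-mers in random sequence none passed the threshold, and 20 of 20 implanted 8-mers were found. A 19 bp sequence implanted in 669 of 1338 windows was recovered in 669, with 686 windows above the threshold in all. The implanted sites were close variants that match the starting pattern, in random sequence. The share of more varied real sites that is missed is therefore not known from this. Fisher's exact test fell below 0.05 in 10 of 200 random sets, and 200 of 200 planted shoulder summits were removed. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.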

Results

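The series measured where the chromatin protein Pita sits in the genome of Drosophila melanogaster embryos. Pita is a zinc-finger protein of the architectural (insulator) class, known to bind boundaries of the bithorax complex. Flies carried a transgene for Pita fused to eGFP, and, per the description in the labels, an anti-GFP antibody precipitated sonicated chromatin from embryos of both sexes aged 0 to 24 hours. The labels give 2 libraries of 1 group, biological replicates 1 and 3, so the design holds no contrast between groups. The comparisons below set the replicates against each other and the reproducible peaks against the remaining candidate regions. The pooled candidates were deposited as peaks and background, so the remaining regions include background and are not simply weaker peaks. Read depth is unknown, because the peak lists hold no read counts. Peaks are not replicates, so the p-values below describe this peak list and do not measure the spread between animals.

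The reproducible list (the authors' optimal list by irreproducible discovery rate, IDR) held 1338 summits on dm6. All 1338 were the strongest entries of the 30000 pooled candidates by the authors' peak signal, which is each peak's own deposited value and is used here to describe and rank peaks within a list. A structure of this list bears on every count of peaks. Of the 1338 summits, 258 lay within 300 bp of a stronger one, 255 of them to its right on the plus strand and 3 to its left, at a median distance of 204 bp. The list on dm3 had the same structure, with 231 to the right and 2 to the left among 1265 summits. The 19 bp sequence described further on lay within 50 bp of 9.30% of these shoulder summits (24 of 258) and of 71.4% of the stronger summits beside them (175 of 245). Counts over all 1338 summits therefore include neighbouring summits of one region. Going from the strongest summit down, dropping each one within 300 bp of a summit already kept removed 246 and left 1092 peaks, and values for these peaks stand beside the main ones for the planned counts of regions. That step was chosen after the data were examined.

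**Figure D1:**
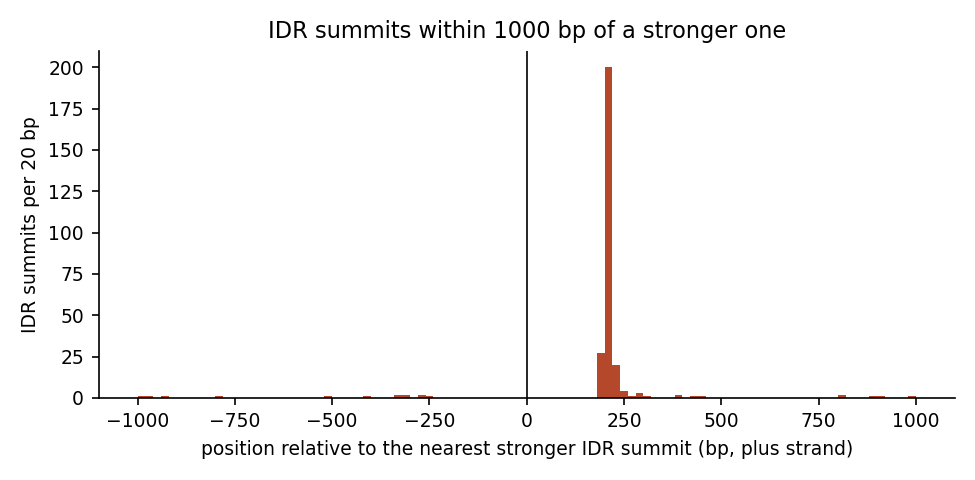
Position of IDR summits (dm6) relative to the nearest stronger IDR summit within 1000 bp, in bp on the plus strand, as the number of summits per 20 bp. Within 300 bp, 255 summits lie to the right of the stronger summit and 3 to the left.

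The strongest regions of replicates 1 and 3 largely overlapped. Of the 1338 strongest candidates of replicate 1, 1180 (88.2%) had a summit within 100 bp among the 1338 strongest of replicate 3. Of the 1338 IDR summits, which were selected for being found in both, 97.2% had a candidate summit of replicate 1 within 100 bp (95% exact Clopper-Pearson interval 96.2 to 98.0) and 98.9% had one of replicate 3 (98.2 to 99.4). The peak upstream of Socs36E, a negative regulator of JAK/STAT signalling, ranked 1 in both. Across the 1291 peaks matched in both, Pearson's r of the log2 signal was 0.930 and Spearman's rank correlation 0.947. These are correlations across peaks, which are not independent replicates. The rank correlation was 0.954 across the 660 of these among the 669 peaks of higher signal, and 0.648 across the 631 in the remainder of the list. Signal in the list had a minimum of 144, a median of 491 and a maximum of 4711. The remainder therefore spans a narrower log2 range, which can lower a correlation by itself.

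Of the 15 strongest peaks, 12 had their summit within 500 bp of a transcription start site (TSS). The highest signal, 4711, was at 2L 18152226 to 18152905, with its summit 104 bp from the TSS of Socs36E. Tlk, which encodes Tousled-like kinase, had a summit at X 3719848, 159 bp from its TSS, with a signal of 4593. ATPsynC, a subunit of mitochondrial ATP synthase, had one at 3R 31219708, 78 bp from its TSS, with a signal of 4576. RpL30, a protein of the large ribosomal subunit, had one at 2L 19009369, 63 bp from its TSS, with a signal of 4436. The actin-binding gene cib followed at X 4105911 and the tyrosine kinase gene Abl at 3L 16648000, at signals of 4357 and 4156. Among the 15 strongest peaks, MCU (the mitochondrial calcium uniporter), CG7655, Atg8a (a ubiquitin-like protein of autophagy), T48 (needed for mesoderm invagination), Lk6 (a protein kinase) and ec also had promoter summits. The peaks nearest CG6465, CG14082 and CG9380 were intergenic, at 3R 10675320, 3L 19140516 and 2R 25183164. Each of the 15 ranked between 1 and 18 in either replicate alone.

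Promoters held most of the reproducible peaks. Of the 1338 summits, 60.8% lay within 500 bp of an annotated TSS (95% exact interval 58.1 to 63.4). The share was 14.9% among the 28662 other candidates and 13.7% among random positions. Coding exons showed the opposite, with 1.12% of IDR summits and 19.5% of other candidates, and introns held 13.5% against 38.8%. Summits in 3' UTRs made up 3.21% against 7.82%. The odds ratio for promoters was 8.86 (Fisher's exact test, two-sided, adjusted p = 6.29e-301 over 7 classes), and 6 of the 7 classes passed the adjusted threshold. With shoulder summits dropped, 58.1% of 1092 summits were promoter summits and the odds ratio was 8.22; 5 classes passed, other exons no longer doing so (exact test, adjusted p = 0.0881). Intergenic summits were more frequent than among other candidates (20.5% against 17.0%, odds ratio 1.26) but less frequent than among random positions (27.2%), where the odds ratio turned to 0.688. Among the 669 peaks of higher signal the intergenic class did not pass (odds ratio 1.09, exact test, adjusted p = 0.378).

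**Figure D2:**
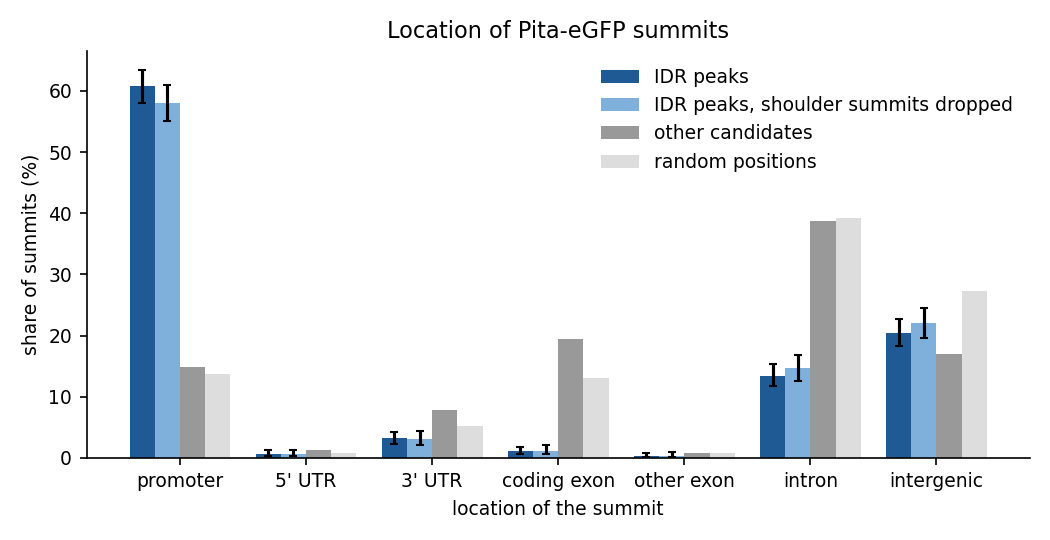
Share of summits (%) in each annotated location for all 1338 IDR peaks, for the 1092 left when shoulder summits are dropped, for other pooled candidates and for random positions. Error bars on the IDR bars are 95% exact binomial intervals, and promoters hold 60.8% of IDR summits and 14.9% of other candidates.

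Peaks at promoters were also stronger. The median signal was 596 at the 813 promoter peaks and 389 at the 525 others, a difference of 0.62 on the log2 scale (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples give). The difference was 0.95 with shoulder summits dropped, with medians of 813 and 421, and 0.25 among the 669 peaks of higher signal (permutation test, p = 0.00656).

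Counted per gene, head-to-head genes had promoter peaks more often than other genes. Of 5052 protein-coding genes with an opposite-strand protein-coding TSS within 1000 bp upstream, 7.40% had an IDR summit within 500 bp of a TSS, against 4.72% of the other 8893 genes. The odds ratio was 1.61 (Fisher's exact test, two-sided, p = 1.12e-10), and 1.62 with shoulder summits dropped. Because a peak between such genes can count for both, each pair was also counted once, which gave 8.21% of 2423 pairs and an odds ratio of 1.81. A pair counted when either of its genes had a peak, and it was set against single genes. A higher share can come from that counting alone, so an excess at head-to-head promoters beyond it was not shown.

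The X chromosome held more reproducible peaks than its share of candidates. It carried 20.8% of IDR summits and 14.4% of other candidates (odds ratio 1.55, Fisher's exact test, two-sided, adjusted p = 7.42e-09 over 7 arms). The excess was smaller against the length of the arms, of which X makes up 17.6% (odds ratio 1.23, exact binomial test, two-sided, adjusted p = 0.0153). The density was 11.8 summits per Mb on X, and from 8.82 on 2R to 9.91 on 3R among the large autosomal arms; the small arm 4 had 11.9 per Mb from 16 summits. With shoulder summits dropped X had 9.77 per Mb, 21.1% of summits and an odds ratio of 1.58. Arms 2L, 2R, 3L, 3R, 4 and Y did not pass the adjusted threshold. Among the 669 peaks of higher signal X did not pass either (odds ratio 1.25, exact test, adjusted p = 0.0837).

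Genes for cytoplasmic ribosomal proteins held IDR peaks more often than other genes, the single list of 12 fixed before the data were examined to pass its test. Lists were not tested against each other. Of 92 such genes, 21 had an IDR summit within 500 bp of a TSS (22.8%), against 5.58% of all other protein-coding genes. RpL30, RpL22 and RpL23 had the strongest of these peaks, at signals of 4436, 2501 and 1973, with summits 63, 101 and 100 bp from a TSS. The odds ratio was 5.0 (Fisher's exact test, two-sided, adjusted p = 4.12e-07 over 12 lists). Against genes with any pooled candidate at a TSS it was 3.89 (exact test, adjusted p = 2.65e-04), with 21 of 42 members holding an IDR peak. Without shoulder summits the count stayed at 21 of 92, and the odds ratio against all other genes was 5.12 (exact test, adjusted p = 2.90e-07).

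The other 11 lists did not pass the threshold. Mitochondrial ribosomal protein genes had peaks at 5 of 73 members, led by mRpL13, mRpL1 and mRpL47 at signals of 2798, 2187 and 2060. Respiratory chain genes had peaks at 4 of 84, led by ATPsynC, UQCR-Q and ATPsynF (4576, 2664 and 2045). DNA replication genes had peaks at 4 of 31. Orc4, a subunit of the origin recognition complex, had the strongest, at 2R 24797487, 73 bp from its TSS, with a signal of 1999.9 and rank 105. The licensing factor gene dup and the helicase gene Mcm7 followed at 597 and 489, and Gnf1 was counted through a shoulder summit. Cell cycle genes had 1 of 30, the spindle checkpoint gene mad2 at 2158. Proteasome genes had 2 of 34, Rpt4 and Rpt6 at 668 and 407. Polycomb and Trithorax group genes had 3 of 27, trx, Pc and kis at 1651, 1627 and 847. Embryonic patterning genes had 2 of 37, cnc at 2009 and the maternal determinant bcd at 482. Hsp83 was the single heat shock gene with a peak among 17, at 162. None of the 8 Hox genes and none of the 22 testis genes, a control list, had a promoter peak.

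Insulator and architectural protein genes had peaks at 3 of 19: fs(1)h at 1816, pita at 534 and BEAF-32 at 166.5. At pita the promoter summit, 2R 23554393, was a shoulder summit. The stronger summit at 23554191 had a signal of 1352, held the 19 bp sequence and lay in an intron 521 bp from the nearest TSS, just beyond the 500 bp window. With shoulder summits dropped the list had 2 of 19 members and DNA replication genes had 3 of 31.

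**Figure D3:**
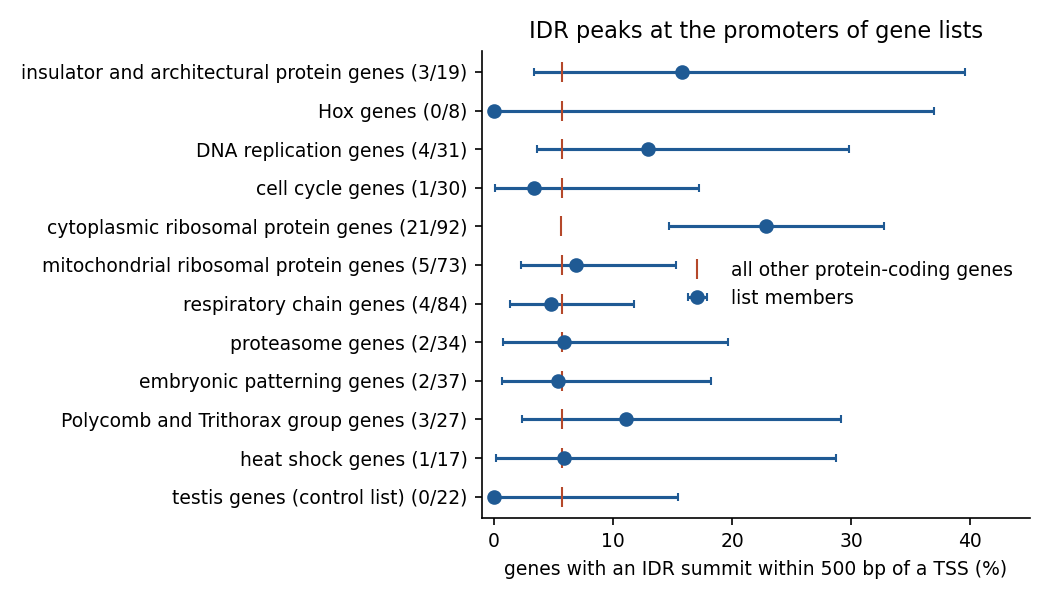
Share of genes (%) in each of 12 lists with an IDR summit within 500 bp of a TSS, with 95% exact binomial intervals; ticks mark all other protein-coding genes. Cytoplasmic ribosomal protein genes (21 of 92) lie above the other genes, at 22.8%.

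The bithorax complex, which holds the Hox genes Ubx, abd-A and Abd-B, carried more peaks than its length on 3R predicts. Between 3R 16656623 and 16972236 there were 12 IDR summits against 3.13 from the rate on 3R (ratio 3.84, exact binomial test, two-sided, p = 9.37e-05). With shoulder summits dropped, 10 lay there against 2.54 (ratio 3.94, exact test, p = 2.83e-04). The strongest, at 3R 16969483 to 16970218 with its summit at 16969744, lay in an intron of Abd-B with a signal of 3492 and rank 16. A further summit in an Abd-B intron, 16957956, had a signal of 1440. The peak at 16798624, intergenic beside lncRNA:CR45750, had 2068, that at 16869367 in an intron of lncRNA:iab8 had 763, and that at 16748727 in an intron of lncRNA:bxd had 618. The summits at 16969980 and 16798854 were shoulder summits of the peaks at 16969744 and 16798624. Summits at 16899536, 16882839 and 16898599 in lncRNA:iab8 had signals of 492, 291 and 248. The nearest IDR summit lay 1170 bp from a TSS of Abd-B, 4821 bp from one of abd-A and 14301 bp from one of Ubx. Boundary elements are not part of the annotation used here, so peaks were not assigned to them.

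**Figure D4:**
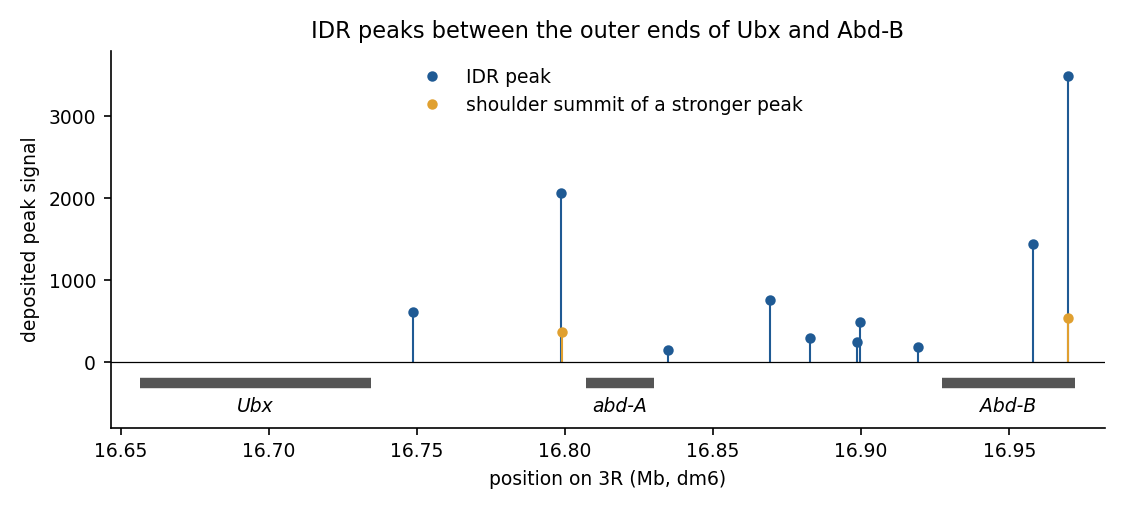
Deposited peak signal of the IDR summits along the bithorax complex (3R, Mb, dm6), with the spans of Ubx, abd-A and Abd-B as bars. The strongest summit, at 16969744 in Abd-B, has a signal of 3492, and the 2 shoulder summits are marked in another colour.

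Short sequences were enriched under the summits. Of 3369 tested 8-mers, 186 were more frequent within 50 bp of the summit than in a window centred 250 bp downstream (exact McNemar test, two-sided, Benjamini-Hochberg), and 29 were less frequent. Downstream and upstream here mean right and left on the plus strand, whatever the direction of nearby genes. Against a window 250 bp upstream 51 were enriched. With shoulder summits dropped the downstream and upstream windows gave 271 and 283. CTCAAACC lay under 56 summits and in 3 flanks (exact p = 1.19e-13), and CACAAACC under 51 and in 2. AGATGGCG (67 and 7), AGGTGGCG (49 and 2) and GCGCCACC (50 and 2) resemble the core bound by the insulator protein CTCF. CTCAAACC was chosen on these peaks and lay under 4.19% of them. In a split of the peaks in chromosomal order, the top 8-mer of either part was counted in the other: AGATGGCG lay under 4.33% of summits against 0.897% of flanks, and CACAAACC under 3.59% against 0.149%. Peaks with CTCAAACC had a median signal of 823 and the others 480 (permutation test, two-sided, p = 0.00705).

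The 8-mers ending in AACC formed part of a longer sequence. A 19 bp matrix grown from them had the consensus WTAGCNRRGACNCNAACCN. Learned on one part of the peaks and counted in the other, it lay within 50 bp of 53.4% of summits (95% exact interval 50.7 to 56.1) and in 5.01% of flanks. The starting pattern was taken from all peaks, so the parts are not fully independent. The share was 57.9% at promoter peaks and 46.5% at others. Over the 1092 peaks left when shoulder summits were dropped it was 64.2%, with 72.1% at promoter peaks and 53.3% at others. It fell with signal, from 86.0% among the 335 peaks of highest signal to 25.4% among the 334 of lowest. With shoulder summits dropped it ran from 87.9% to 38.5% in groups of 273. The strongest bithorax peak and the peaks of Socs36E, Tlk, ATPsynC, RpL30 and Orc4 held it, while that nearest CG9380 did not. In the bithorax complex 5 of 12 summits held it (41.7%) and 0 flanks did (exact McNemar test, p = 0.0625).

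**Figure D5:**
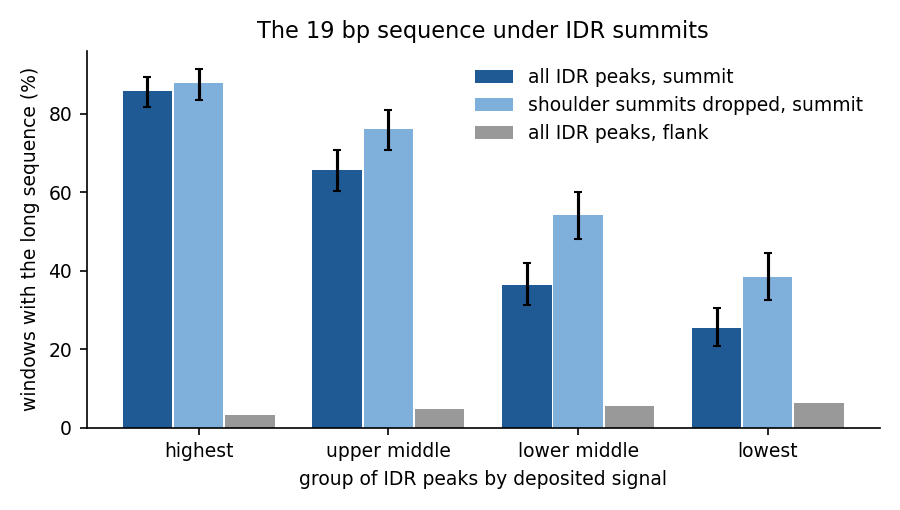
Share of windows (%) holding the 19 bp sequence at the summit and in the flank, by deposited signal in 4 groups of peaks, for all IDR peaks and with shoulder summits dropped. Error bars are 95% exact binomial intervals, and the summit share over all IDR peaks runs from 86.0% in the highest group to 25.4% in the lowest.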

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

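The tests on shoulder summits and on all genome-wide matches of the sequence were chosen only after the result was seen. The other tests named here were written down before their results were computed, but after the peaks had been explored.

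The dm3 list holds 7 IDR summits on heterochromatic or unplaced scaffolds, and 5 remain when shoulder summits are dropped. Whether the same sequences lie on the dm6 arms, and so already among the dm6 peaks, was not examined. The strongest, on 3RHet at 2107243, had a signal of 1099 and rank 320.

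Among the 1338 pooled candidates ranked just below the IDR list, 156 held the 19 bp sequence at the summit (11.7%) and 64 in the flank (4.78%; exact McNemar test, p = 1.13e-10). Of these candidates 191 lay within 300 bp of an IDR summit. Among the next 1338 candidates away from IDR and stronger summits the share was still 11.7% against 4.71% (exact test, p = 5.32e-11), so some binding may extend below the threshold. In the following rank group it was 6.80% against 5.61% (exact test, p = 0.230).

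IDR summits within 300 bp of a stronger one lay to its right in 255 of 258 cases. Separate sites side by side are argued against, since 9.30% of shoulder summits held the 19 bp sequence, against 71.4% of the stronger summits beside them. A candidate explanation is that the same site was called again at a fixed step, which was not decided by a test. The lower share to the right over both strands of the sequence was 97.5%, but with 3 shoulder summits to the left in all it could not have come out otherwise. The caller is not given in the sources used here, so the step that made them stays open.

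For the high share of IDR peaks at promoters, open promoters caught without the sequence would leave promoter peaks with no more of it than their flanks. However, 57.9% held it, against 4.92% of flanks. With shoulder summits dropped the shares were 72.1% and 4.57%. Of all 9735 genome-wide matches of the sequence 18.4% lay at promoters (1.34 times the share of random positions), against 60.8% of IDR peaks. However, 960 of the matches lay under an IDR peak, and matches that are not binding sites would fall near the random share. The total could therefore hardly have reached that of the peaks, and it does not decide whether the sequence's own position is the whole cause. Matches outside IDR peaks lay at promoters 0.970 times as often as random positions. Leaving out bound matches removes mostly promoter ones, so that value decides nothing either. Of the matches at promoters 34.9% lay under an IDR peak, and of those elsewhere 4.21%. A hypothesis that stays open is that open chromatin at promoters may decide which matches are bound; no accessibility data were used here, and the promoter peaks without the sequence are not accounted for.

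The CTCF core (AGATGGCG or AGGTGGCG) lay under 8.52% of IDR summits (10.2% with shoulder summits dropped) and in 0.673% of flanks. Promoter base composition is argued against, since promoter IDR peaks held the core 5.07 times as often as other promoter candidates, and 25.4% of the peaks with it were promoter peaks at all. The core was chosen on these same IDR peaks, and 29 of the 813 promoter peaks held it, so the comparison is not independent. Peaks with the core held the 19 bp sequence in 26.3% of cases and the others in 56.0% (Fisher's exact test, p = 1.01e-09), and in 26.1% and 68.5% with shoulder summits dropped. A lower share would follow if these regions were held through another protein at its own sequence, a hypothesis found and tested on the same peaks. No biological contrast in the design bears on it. Peaks with the core were also promoter peaks less often than the others (25.4% against 64.1%). Peaks outside promoters held the 19 bp sequence less often than promoter peaks (46.5% against 57.9%). The comparison was not split by location, so location may account for part of the gap.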

How the results depend on the processing

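The alternatives without shoulder summits, those of the 19 bp sequence, ranks of named peaks in either replicate alone, head-to-head pairs counted once and transposable elements counted as genes were chosen only after the result was seen; the rest were fixed before the data were examined. The promoter, head-to-head, bithorax, signal and CTCAAACC results kept their direction and side of the threshold under each alternative run, with odds ratios of 5.56 to 12.04 for promoters. The 8-mer count is the result that the flank decides: 186 with the downstream flank, 51 with the upstream flank, and 271 and 283 for the downstream and upstream flanks when shoulder summits were dropped. Upstream flanks of shoulder summits lie at or near the stronger summit, and the asymmetry went when shoulder summits were dropped. Whether those flanks hold the stronger summit's sequence was not counted. The 8-mer of lowest p was CACAAACC without replicate 3, AGATGGCG without shoulder summits, GATGGCGC in 100 bp windows and GCGCCACC with the upstream flank. Arms past the threshold numbered 1 in the main analysis, 0 among the 669 peaks of higher signal, and 1 to 3 with either replicate left out (3 without replicate 3). The intergenic odds ratio of 1.26 turned to 0.688 against random positions; the background differs by construction. IDR summits found in replicate 1 (97.2%) came to 99.9% by 1 bp overlap, 99.7% within 250 bp, 99.1% for the higher-signal peaks and 98.4% without shoulder summits; in replicate 3 (98.9%) to 100% and 99.9% by overlap and within 250 bp. Spearman's rank correlation (0.947) was 0.923 within 250 bp, 0.954 for the higher-signal peaks and 0.974 without shoulder summits; the cause was not tested. No paired analysis was possible because there is 1 group.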

Other observations

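The test of the share of other candidates on X was chosen only after the result was seen. Among genes for ribosomal proteins, 21 of 92 cytoplasmic ribosomal protein genes and 5 of 73 mitochondrial ones had an IDR promoter peak, and the difference between these lists was not tested. Further cytoplasmic members with peaks were RpL17 and RpL13A, at signals of 1720 and 1634, chosen after their values were seen.

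IDR peaks were 1.23 times as dense on X as on the large autosomal arms (95% exact interval 1.08 to 1.41). X held 14.4% of other candidates and 17.6% of the length of the arms. A count of candidates does not measure the level of background. The dose of X in embryos of both sexes was also not allowed for. Whether background is higher on X was therefore not decided. Genome-wide matches of the 19 bp sequence were 1.09 times as dense on X (1.04 to 1.15), an interval that crosses the lower bound of the peak ratio, so whether more matches account for the peaks cannot be told apart from a smaller effect. Matches on X lay under an IDR peak in 12.5% of cases and autosomal ones in 9.29% (Fisher's exact test, p = 3.83e-05).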
